A study of Mus musculus with 15 samples.

How the data were processed

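Splenic B cells binding the hapten NP were sorted from mVh186.2 transgenic mice in 2 screens, per the labels. Naive cells were on 3 arrays and memory cells on 4 arrays in the first screen, sorted on a FACSVantage and labeled with EnzoBio reagents. AA4.1-negative naive cells and memory cells were on 4 arrays each in the second, sorted on a FACSAria and labeled with a MessageAmp kit. The labels call the replicates biological. They do not state whether the second-screen memory arrays EK, FG and HJ are pools of mice; if so, the SD between memory arrays of that screen is not one between single mice. Total RNA was prepared with RNeasy columns and the labeled RNA carried biotin. Each of the 15 arrays gave values for 45101 probe sets, of which 64 controls were left out of the tests.

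The deposited value of each array is an intensity on a linear scale. For the second screen the authors summarized it with GCRMA, whose version is not given in the sources used here, and the software of the first screen is not given in the sources used here. The deposited tables of each screen also hold pooled columns, a ratio of memory over naive cells and a p-value of that comparison by the authors. In the deposited table of the first screen the pooled columns equal the sums of the arrays rather than their means, so the deposited ratio is 1.33 times the ratio of means; the pooled columns of the second screen equal the means. The deposited p-value equals an equal-variance t-test on the linear intensity of the same screen's arrays, checked within 0.0001. The ratio and the p-value of the authors were not used in the comparisons.

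Values were taken as log2(intensity + 1). A probe set was kept where it lay above the median of all values of its screen (log2 6.98 in the first and 4.73 in the second screen) on at least 3 arrays of the first or 4 of the second, the size of the smaller group; 23813 and 22638 probe sets were kept. Symbols in the files were brought to current names with a table of reference symbols, and for each gene the probe set with the highest mean was tested; probe sets without a symbol were tested on their own. This left 15872 genes and probe sets in the first screen and 14706 in the second. Median intensity per array was 103.4 to 153.7 in the first and near 25 in the second screen, and the median standard error of a change was 0.26 and 0.09 on the log2 scale.

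Memory was compared with naive cells in each screen by limma 3.58.1 (lmFit and eBayes with an intensity trend) in R 4.3.3, with Benjamini-Hochberg adjustment per screen and a threshold of 0.05. The overlap of the screens was tested by Fisher's exact test, two-sided. The difference between the screens was tested as a contrast in a limma fit of 4 groups and 15 arrays. The 31 fixed gene lists (memory surface, germinal center, plasma cell, naive follicular, transitional, marginal zone, B-1, receptor signaling, inhibitory receptor, Toll-like receptor, cytokine receptor, chemokine and adhesion, TNF receptor, anti-apoptotic and pro-apoptotic, cell cycle, quiescence, transcription factor, antigen presentation, immunoglobulin constant, interferon, immediate early, purine, mitochondrial, T cell, NK cell, myeloid, dendritic, erythroid, platelet and Y-linked genes) were counted. They were tested by camera with a preset correlation of 0.01 where at least 3 genes were measured, adjusted over the lists, and again with a correlation estimated from the data. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 was used for reading, checks and figures.

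The samples of each group, the tests, the rule for naming genes and the other settings were fixed before the data were examined. Per screen the text names the 10 with the largest rise and the 10 with the largest fall among called genes whose arrays do not overlap, immunoglobulin genes aside. It also names up to 4 called genes, or 2 uncalled, of each list, the 10 largest rises and falls shared by the screens (immunoglobulin genes and Jchain aside), and the 10 with the smallest p for the difference. Some genes selected by this rule are not given here. A set of control genes was checked, of which Igkc, Iglc1, Iglc2, Ighd and Xist are not named in the files. Alternatives were no filter or a stricter filter on dim probe sets, median centring, quantile normalization, a pseudocount of 16, every probe set or the mean of a gene's probe sets, eBayes without the trend or with robust estimates, and array weights. Further ones were a fit of all 15 arrays, a t-test, a fold change of at least 2 as well, fry, the difference of the 2 separate fits, and leaving out each array in turn. Chosen after seeing the data were naive C and memory G of the first screen as a block, the fit without both, the dendritic cell list without Klrd1, and the difference test with the degrees of freedom of each separate fit. The limma test of each screen and 3 versions of the difference test were tried on simulated data with 200 changed genes in 20 simulated sets. Each gene was drawn independently from a normal distribution with its own mean and spread. The simulated arrays thus held no correlation between genes and no arrays that stood apart.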

Results

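Transcript levels were measured by oligonucleotide array in 15 samples of mouse splenic B cells sorted for binding to the hapten NP, from mice with the mVh186.2 transgene, an immunoglobulin heavy chain gene used in responses to NP. The samples fall into 2 screens. In the first screen, 3 arrays of naive cells (A, B and C) stood against 4 arrays of memory cells (D, E, F and G). In the second screen, 4 arrays of AA4.1-negative naive cells (A to D) from mice that also lacked the Jk segments stood against 4 arrays of memory cells (EK, FG, HJ and I) formed after transfer of transgenic splenocytes into AM14/Vk8R transgenic recipients. Whether arrays EK, FG and HJ each hold cells pooled from several mice is not stated in the labels. AA4.1 is the product of Cd93 and marks immature B cells. The median intensity per array ran from 103.4 to 153.7 in the first screen and near 25 in the second, and the number of arrays limits the precision. Chromosomal positions were not used here. Values below are log2 intensities with the SD between arrays, and changes are memory minus naive on the log2 scale with the standard error of the limma fit.

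The first screen asked which transcripts set NP-specific memory B cells apart from naive B cells of the same specificity. S100a6, a calcium-binding protein, had the smallest adjusted p of all genes and stood at 13.91 ± 0.16 in memory against 10.44 ± 0.16 in naive cells (SD, n = 4 and 3), 11.1-fold higher (adjusted p = 8.18e-06). Its relative S100a4 rose by 4.28 ± 0.29 and the LIM-domain protein Pdlim1 by 3.56 ± 0.22. Ighg1, the constant region of a switched antibody class, reached 11.34 ± 0.31 in memory against 7.54 ± 0.24 in naive cells, a rise of 3.80 (adjusted p = 9.48e-05), and Jchain, which joins secreted antibody polymers, rose by 3.46 (adjusted p = 0.000907). Vpreb3, a protein of the B cell receptor assembly pathway, fell from 11.96 ± 0.09 in naive to 9.48 ± 0.35 in memory cells (adjusted p = 0.000323).

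Besides these, the named genes with the largest rises in the first screen were Emp1 (4.96 ± 0.80), Tppp (4.50 ± 0.74), Tubb6 (3.38 ± 0.53), Hepacam2 (3.35 ± 0.21), Prkcz (3.16 ± 0.39), Marveld1 (3.08 ± 0.40) and 2310047C17Rik (2.90 ± 0.23), and Ass1, an enzyme of arginine synthesis, rose by 2.63 ± 0.16. All naive arrays lay below the screen's median intensity for Emp1, Tppp, Hepacam2 and Prkcz, and the naive mean did for Tubb6 (5.67) and Marveld1 (6.30), so the size of those changes depends on how low signals were treated. The largest falls were in Tifa (-3.86 ± 0.61), Wwc2 (-2.78 ± 0.49), Vpreb3, Pde2a (-2.06 ± 0.24), Edaradd (-1.76 ± 0.26), Csrp2 (-1.69 ± 0.21), Cpm (-1.63 ± 0.16), Selenop (-1.51 ± 0.19), Sapcd1 (-1.46 ± 0.22) and H1f2 (-1.40 ± 0.19), and memory arrays lay below the median intensity for Tifa and Wwc2. Memory and naive arrays did not overlap for any of these genes, as the rule for naming the largest changes required. Leaving out 1 array ended some of these calls, namely of Emp1 (adjusted p without memory D 0.18, E 0.172, F 0.173 or G 0.06), Tppp (adjusted p without naive A 0.0822, memory D 0.124, E 0.0889, F 0.118 or G 0.0807), Tubb6 (adjusted p without naive A 0.0605, C 0.0506, memory D 0.0999, E 0.0847 or F 0.107), Tifa (adjusted p without naive A 0.199, B 0.134 or C 0.123), Wwc2 (adjusted p without naive A 0.344, B 0.186, C 0.108, memory D 0.0866, E 0.0807 or F 0.0524), Edaradd (adjusted p without naive A 0.0794, B 0.0826 or memory D 0.0519), Sapcd1 (adjusted p without naive A 0.0918, B 0.0945 or memory F 0.0695), Csrp2 (adjusted p without naive B 0.0505) and H1f2 (adjusted p without naive B 0.0642).

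Genes of B cell subsets moved in both directions in the first screen. Among surface molecules used to subset memory B cells, 1 of 7 measured genes rose, Pdcd1lg2 (PD-L2, 10.62 ± 0.17 in memory against 8.54 ± 0.35 in naive cells, adjusted p = 0.00107), and 4 rose when adjusted over the list alone. Molecules of this list were chosen on memory B cells of this kind, so the list is not independent evidence. The list ranked higher in memory cells by camera (adjusted p = 0.00022; adjusted p = 0.0967 with an estimated correlation). Of 7 genes of B-1 cells, Zbtb32, a transcriptional repressor, rose to 11.52 ± 0.36 from 8.87 ± 0.11 and Plscr1 rose by 1.62 (adjusted p = 0.00563), 2 when adjusted over the list alone. By camera the B-1 cell list ranked higher (adjusted p = 0.00202; adjusted p = 0.0967 with an estimated correlation). Of 11 genes of resting follicular B cells, Fcer2a (CD23) fell by 1.04 (adjusted p = 0.0138) and 2 fell when adjusted over the list alone. By camera the follicular list ranked lower (adjusted p = 0.000237; adjusted p = 0.0967 with an estimated correlation). Marginal zone genes ranked lower with no call among 12 and 4 lower when adjusted over the list alone (camera adjusted p = 0.000132; adjusted p = 0.0967 with an estimated correlation). Cd36 stood at 7.93 ± 0.71 in memory against 10.22 ± 0.86 in naive cells (adjusted p = 0.0637) and Asb2 changed by -0.82 (adjusted p = 0.063). Of 7 genes of transitional cells only Vpreb3 was called and 2 were lower when adjusted over the list alone. Cd93 entered this list by its brightest probe set (7.61 in memory against 7.27 in naive cells), while its other 2 measured probe sets were called lower. With the stricter filter Cd93 was called lower (-3.21, adjusted p = 0.0396). By camera the transitional list ranked lower (adjusted p = 0.0232; adjusted p = 0.348 with an estimated correlation). That call ended under 7 of 11 settings other than leaving out 1 array, among them median centring (adjusted p = 0.0887), and also without naive C (adjusted p = 0.576) or memory D (adjusted p = 0.0707). It ended too with naive C and memory G as a block (adjusted p = 0.0739) and without both (adjusted p = 0.271), 2 settings chosen after seeing the data. In that block Cd36 (adjusted p = 0.000325; 0.000325 to 0.297 over all alternatives) and Asb2 (adjusted p = 0.011; 0.0106 to 0.266 over all alternatives) were called, and 2 marginal zone and 5 follicular genes were called lower. The block also called 3 memory surface genes higher, Pdcd1lg2, Cd86 (adjusted p = 0.00724) and Nt5e (adjusted p = 0.0194). It called Cd24a of the transitional list lower (-0.62, adjusted p = 0.0149). Cd86, Nt5e and Cd24a were chosen after their values were seen. Leaving out 1 array ended the call of Fcer2a (adjusted p without naive B 0.059, memory D 0.052 or F 0.0661).

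Interferon-stimulated genes ranked lower in memory cells of the first screen (camera adjusted p = 1.93e-07; adjusted p = 0.0967 with an estimated correlation). None of 23 was called over all genes and 7 were lower when adjusted over the list alone. Usp18 stood at 9.84 ± 0.41 in memory against 10.93 ± 0.03 in naive cells (adjusted p = 0.063) and Ifi44 at 9.65 ± 0.45 in memory against 10.88 ± 0.24 in naive cells (adjusted p = 0.0637). Cell cycle genes also ranked lower (camera adjusted p = 1.93e-07; adjusted p = 0.171 with an estimated correlation). They had a median change of -0.38 over 32 genes and no single gene called, nor any when adjusted over the list alone. Top2a changed by -0.81 ± 0.19 (adjusted p = 0.126) and Mcm5 by -0.83 ± 0.22 (adjusted p = 0.164). Immediate early genes ranked lower (camera adjusted p = 0.00129; adjusted p = 0.476 with an estimated correlation). Egr3 fell by 1.23 (adjusted p = 0.0482), 1 of 21, and 3 were lower and 1 higher when adjusted over the list alone. In that list Fos, chosen after its values were seen, read 8.32 on memory array G against 13.35 to 14.09 on the other memory arrays, and the list was not called without naive C and memory G (adjusted p = 0.111) or without naive C (adjusted p = 0.0942). Leaving out any 1 array but memory G ended the call of Egr3 (adjusted p without naive A 0.179, B 0.199, C 0.074, memory D 0.071, E 0.073 or F 0.179). Genes of B cell receptor signaling ranked lower with none of 25 called, nor any when adjusted over the list alone (camera adjusted p = 0.00898; adjusted p = 0.348 with an estimated correlation; adjusted p = 0.065 after quantile normalization and 0.0667 without naive C), a call that ended under 5 of 11 settings other than leaving out 1 array. The receptor signaling list was also not called without naive C and memory G (camera adjusted p = 0.177). Lyn changed by -0.45 (adjusted p = 0.153) and Pik3ap1 by -0.39 (adjusted p = 0.292). Extracellular purine genes ranked higher (camera adjusted p = 0.00545; adjusted p = 0.351 with an estimated correlation). The adenosine receptor Adora2a stood at 9.99 ± 0.44 in memory against 7.97 ± 0.29 in naive cells (adjusted p = 0.00745), the 1 called gene of 14, and 4 were higher when adjusted over the list alone. With naive C and memory G as a block, chosen after seeing the data, 5 interferon genes, 3 cell cycle genes, 6 immediate early genes and 2 genes of receptor signaling were called lower and 6 purine genes higher. Among them were Usp18 (adjusted p = 0.00989; 0.00329 to 0.236 over all alternatives), Ifi44 (adjusted p = 0.000686; 0.000294 to 0.247 over all alternatives), Top2a (adjusted p = 0.0198; 0.0198 to 0.896 over all alternatives), Mcm5 (adjusted p = 0.00724; 0.00724 to 0.821 over all alternatives), Lyn (adjusted p = 0.0205; 0.00226 to 0.903 over all alternatives) and Pik3ap1 (adjusted p = 0.0274; 0.0274 to 0.795 over all alternatives).

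The lists that come next were not called as a whole in the first screen. Receptors with single called members were Bmpr1a (2.36, adjusted p = 0.0105) and Il5ra (0.97, adjusted p = 0.0306) among 27 cytokine receptors (4 up and 1 down when adjusted over the list alone). Itgb7 rose (0.86, adjusted p = 0.00906) among 28 chemokine receptors and adhesion molecules (2 and 0). Ptpn22, a phosphatase, rose by 1.40 and Cd72, an inhibitory receptor, fell by 1.19 among 16 inhibitory receptors and phosphatases (1 and 1). The legumain gene Lgmn fell by 1.20 beside Pdcd1lg2 among 18 antigen presentation genes (3 and 1). Jchain and Fkbp11 (1.23, adjusted p = 0.0438) rose among 12 genes of antibody-secreting cells (2 and 0). Pmaip1 rose (1.06, adjusted p = 0.0155) among 13 pro-apoptotic factors (1 and 1). No gene was called among 10 germinal center genes (0 and 3 when adjusted over the list alone; Bcl6 (-1.16), Cxcr4 (-1.37)) or 25 B lineage transcription factors (0 and 0; Zbtb20 (0.98)). Nor was any called among 17 Toll-like receptors and adaptors (1 and 0; Irak3 (0.69), Tlr1 (-0.69)) or 14 TNF receptors and ligands (0 and 1; Tnfrsf13c (-0.48), Tnfrsf1b (0.57)). None was called either among 12 anti-apoptotic factors (0 and 0; Birc3 (-0.24), Pim1 (0.44)) or 19 quiescence genes (2 and 2; Slfn2 (-0.65), Klf3 (0.51)). The same held for 44 respiratory chain subunits (0 and 0; Cox5a (-0.31), Sdhd (0.35)). With naive C and memory G as a block, chosen after seeing the data, 8 of these uncalled genes were called: Bcl6 (adjusted p = 0.000665; 0.000665 to 0.59 over all alternatives), Cxcr4 (adjusted p = 0.0167; 0.0167 to 0.507 over all alternatives), Irak3 (adjusted p = 0.0182; 0.00167 to 0.667 over all alternatives), Tlr1 (adjusted p = 0.00139; 0.000797 to 0.808 over all alternatives), Tnfrsf13c (adjusted p = 0.011; 0.011 to 0.428 over all alternatives), Pim1 (adjusted p = 0.0496; 0.026 to 0.985 over all alternatives), Slfn2 (adjusted p = 0.0196; 0.00587 to 0.341 over all alternatives) and Klf3 (adjusted p = 0.0161; 0.00121 to 0.968 over all alternatives). In that block the B lineage transcription factors had 3 called lower (1 up and 5 down when adjusted over the list alone), Bcl6 and, chosen after their values were seen, Bach2 (-1.11, adjusted p = 0.00182) and Pax5 (-1.91, adjusted p = 0.0258). Without naive C and memory G, 2 of that list were called lower, Bach2 and Bcl6, and Pax5 was not called. The block called 0 up and 2 down among germinal center genes, 1 and 2 among Toll-like receptors, 0 and 2 among TNF receptors, 1 and 0 among anti-apoptotic factors, 2 and 3 among quiescence genes and 0 among respiratory chain subunits. Among lists with single calls it called 4 and 2 cytokine receptors, 3 and 3 chemokine receptors and adhesion molecules, 1 and 1 inhibitory receptors, 3 and 3 antigen presentation genes, 3 and 0 genes of antibody-secreting cells and 1 and 1 pro-apoptotic factors. Of the single calls some ended when 1 array was left out: Il5ra (adjusted p without naive A 0.135, B 0.163, C 0.0506, memory D 0.106 or F 0.123), Itgb7 (adjusted p without naive A 0.0512 or B 0.0593), Cd72 (adjusted p without naive A 0.14, B 0.154, memory D 0.071, E 0.052 or F 0.109), Fkbp11 (adjusted p without naive A 0.179, B 0.196, C 0.055, memory D 0.108, E 0.127, F 0.106 or G 0.0561) and Pmaip1 (adjusted p without naive B 0.099, memory D 0.0767, E 0.073 or F 0.0711). The median of a list was negative and its mean positive for genes of antibody-secreting cells (-0.08 and 0.37, camera up), inhibitory receptors (-0.07 and 0.12, camera down) and cytokine receptors (-0.02 and 0.28, camera up). Germinal center genes had a median of 0.02 and a mean of -0.20 (camera down). Under median centring the medians of the germinal center (-0.17), chemokine and adhesion (-0.13) and antigen presentation (-0.18) lists turned negative, and after quantile normalization camera turned upward for respiratory chain subunits (adjusted p = 0.797).

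Genes listed as markers of other cells were measured beside these groups in the first screen, and which cells carried their transcripts was not tested. Myeloid genes ranked higher in memory cells (camera adjusted p = 0.00125; adjusted p = 0.0967 with an estimated correlation) with none of 18 called and 4 higher when adjusted over the list alone. Lyz2 stood at 10.97 ± 0.49 in memory against 9.52 ± 0.50 in naive cells (adjusted p = 0.0785) and Cd68 at 9.22 ± 0.12 in memory against 8.18 ± 0.42 in naive cells (adjusted p = 0.0852). With naive C and memory G as a block, chosen after seeing the data, 4 myeloid genes were called higher, among them Lyz2 (adjusted p = 0.0196; 0.000854 to 0.312 over all alternatives) and Cd68 (adjusted p = 0.00531; 0.00134 to 0.351 over all alternatives), and of dendritic cell genes Cd83 (adjusted p = 0.0116; 0.0116 to 0.504 over all alternatives) was called lower. Lck fell by 0.95 (adjusted p = 0.0325), the 1 called T cell gene of 8 (median 0.22, mean 0.01, camera down, 1 up and 1 down when adjusted over the list alone). The block also called the T cell gene Cd2 higher (0.37, adjusted p = 0.0493, and 0.0167 to 0.813 over all alternatives). Without naive C and memory G, Zap70, chosen after its values were seen, was called higher (1.79, adjusted p = 0.0278). Car2 fell by 1.15 (adjusted p = 0.0256) among 8 erythroid genes (2 up and 1 down when adjusted over the list alone), a list with a median of 0.78 and a mean of 0.95. It was not called (camera adjusted p = 0.102; adjusted p = 0.476 with an estimated correlation), but was after median centring (adjusted p = 0.00801) and without naive B (adjusted p = 0.00479). Alas2 (8.40 ± 0.95 in memory against 4.79 ± 1.69 in naive cells, adjusted p = 0.1) and Hba-a1 (13.52 ± 0.91 in memory against 11.72 ± 0.81 in naive cells, adjusted p = 0.19), chosen after their values were seen, read higher in memory cells and were not called. Alas2 was called with naive C and memory G as a block (adjusted p = 0.0306, the 1 erythroid gene called higher, 3 when adjusted over the list alone) and without both (adjusted p = 0.0359). No gene was called among 4 NK cell (Ccl5 (-1.13), Prf1 (0.78)), 7 dendritic cell (Cd83 (-0.74), Flt3 (-0.68)), 5 platelet (Pf4 (0.41), Treml1 (-0.51)) or 4 Y-linked genes (Ddx3y (-0.47), Kdm5d (-0.45)). Adjusted over the list alone, 1 dendritic cell gene was lower and 0 genes passed in the other lists. The calls of Lck and Car2 ended without single arrays: Lck (adjusted p without naive A 0.174, B 0.199, memory D 0.109, E 0.118 or F 0.079) and Car2 (adjusted p without naive B 0.0915, memory D 0.0756, E 0.0741 or F 0.109). Platelet genes had a median of -0.07 and a mean of 0.01 (camera down). The B cell genes Cd79a (-0.01, adjusted p = 0.997) and Ighm (-0.06, adjusted p = 0.93) were not called. Ighm is 1 of the 2 measured immunoglobulin constant regions beside Ighg1 (1 up and 0 down when adjusted over the list alone). Cd93 was not called on its brightest probe set (0.34, adjusted p = 0.853), while its other 2 measured probe sets were called lower, one of them at 6.05 ± 0.88 in memory against 9.27 ± 0.11 in naive cells.

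**Figure D1:**
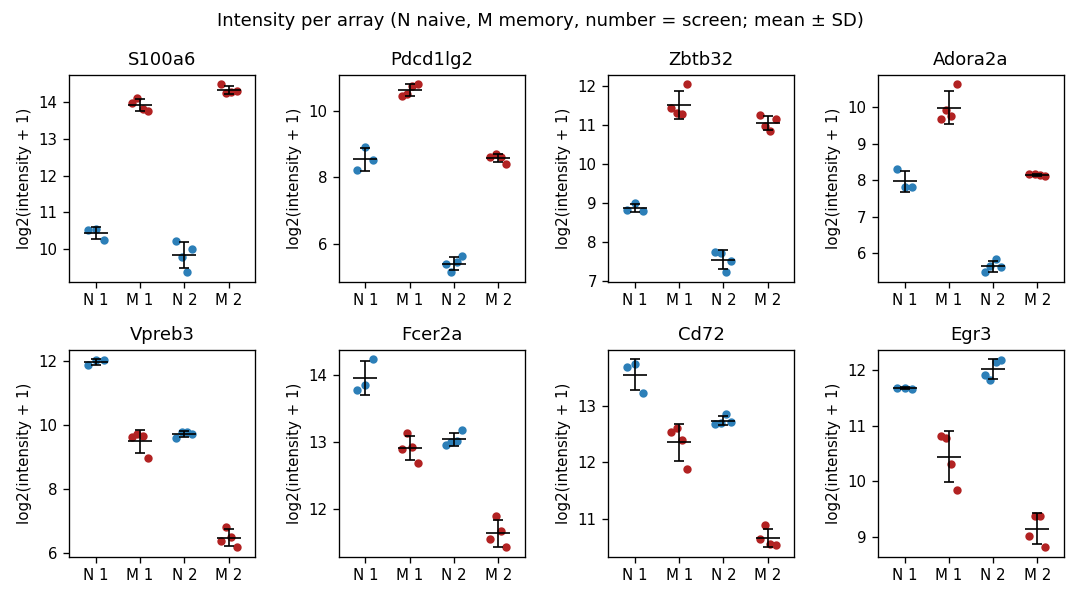
Log2 intensity (intensity plus 1) on each array for 8 named genes, in naive (N, blue) and memory (M, red) cells of the first (1) and second (2) screen; bars are mean and SD. S100a6, Pdcd1lg2, Zbtb32 and Adora2a were higher and Vpreb3, Fcer2a, Cd72 and Egr3 lower in memory cells of both screens, without overlap of the arrays within a screen.

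By limma with Benjamini-Hochberg adjustment, 131 of 15872 genes and unassigned probe sets were called in the first screen, 101 higher and 30 lower in memory cells, and 104 of them changed at least 2-fold. Unadjusted, 1577 had a p under 0.05. Memory and naive arrays did not overlap for 11.3% of all tested, where chance gives 5.71%. On naive C and memory G the ratio of the 3′ to the 5′ actin control probe set was 1.15 and 1.12, against 2.77 to 4.22 on the other 5 arrays. Among those 5 it was 4.185 and 4.224 on naive A and B and 3.412, 2.774 and 4.053 on memory D, E and F. Their Gapdh ratios were 2.88 and 3.42 on the naive arrays and 1.87, 1.60 and 2.24 on the memory arrays. With these arrays as a block, chosen after seeing the data, 707 were called (363 higher, 344 lower). Without both arrays it was 879 (404 higher, 475 lower), each including all 131. As the 3′ to 5′ ratios of the other 5 arrays part by group, the calls without both arrays cannot be told apart from that difference. The calls of the block may hold part of it, which was not tested. The count was 70 without naive A, 58 without naive B, 72 without memory D, 83 without memory E and 65 without memory F. Median centring gave 65 and moved the median change of all genes from 0.02 to -0.18. Camera called 11 lists, and 0 with an estimated correlation.

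**Figure D2:**
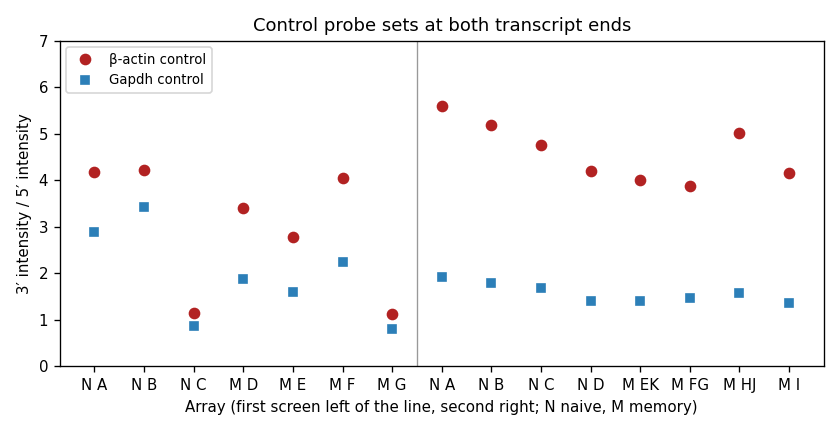
Ratio of 3′ to 5′ intensity of the β-actin (circles) and Gapdh (squares) control probe sets on each array; naive (N) and memory (M), the first screen left of the line. Naive C (1.15) and memory G (1.12) of the first screen lie below the other actin ratios.

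The second screen put the same question to memory cells formed after transfer and to naive cells without the AA4.1-positive fraction. Crisp1, a cysteine-rich secretory protein, rose to 11.35 ± 0.16 from 3.91 ± 0.23 (SD, n = 4 and 4; adjusted p = 5.25e-09), a level at which naive cells lay below the screen's median. S100a4 rose by 5.67 ± 0.10 and S100a6 by 4.50 ± 0.16, 22.6-fold. Ighg1 stood at 10.50 ± 0.33 in memory against 5.18 ± 0.74 in naive cells (adjusted p = 7.4e-06). The scavenger receptor Cd36 fell from 10.03 ± 0.29 to 4.82 ± 0.48 (adjusted p = 1.11e-06), Vpreb3 from 9.71 ± 0.09 to 6.47 ± 0.27, and Cd93 from 7.65 ± 0.42 to 4.26 ± 0.41 although the naive cells had been sorted without AA4.1.

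Further rises among the largest of the second screen were in Tppp3 (6.02 ± 0.28), Hepacam2 (5.85 ± 0.29), Tppp (5.62 ± 0.21), Prkar2b (5.15 ± 0.18), a regulatory subunit of protein kinase A, Osbpl3 (4.91 ± 0.51), D430019H16Rik (4.82 ± 0.24) and Tubb6 (4.76 ± 0.20). All naive arrays lay below the screen's median for Tppp3 and D430019H16Rik, and the naive mean did for Tppp (4.27), Osbpl3 (4.00) and Tubb6 (4.35). Further falls were in Dusp4 (-3.66 ± 0.23), Csrp2 (-3.53 ± 0.30), BC030863 (-3.50 ± 0.19), Tifa (-3.49 ± 0.16), Ifi44 (-3.04 ± 0.16), Il12a (-3.01 ± 0.15) and Pcp4 (-2.97 ± 0.10). Memory arrays lay below the median for Dusp4, Csrp2, Tifa and Cd93, and BC030863 had 1 other probe set called higher. Arrays did not overlap between memory and naive cells for any of these, as the same rule required.

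Of 8 surface molecules used to subset memory B cells, 4 rose and 2 fell in the second screen (4 and 2 when adjusted over the list alone, which is not independent evidence). Pdcd1lg2 stood at 8.58 ± 0.13 in memory against 5.40 ± 0.20 in naive cells, the costimulatory ligand Cd80 at 7.06 ± 0.24 in memory against 4.57 ± 0.45 in naive cells (adjusted p = 4.5e-05). Cd44 rose by 0.86 and Cd27 fell by 1.12 (camera adjusted p = 0.074). Without naive B the memory surface list was called higher (camera adjusted p = 0.0179). Genes of resting follicular cells fell in 7 of 11 cases and rose in 1, the quiescence factor Klf2 (1.00). Fcer2a fell by 1.40, Bach2 by 1.60, Satb1 by 1.13 and the inhibitory receptor Btla by 0.92 (7 down and 1 up when adjusted over the list alone). By camera the follicular list ranked lower (adjusted p = 0.00164; adjusted p = 0.398 with an estimated correlation). Of 7 genes of transitional cells 5 fell, with Vpreb3 and Cd93 also Bcl2l11 (-1.82) and Il7r (-1.41), 5 when adjusted over the list alone. By camera the transitional list ranked lower (adjusted p = 0.00164; adjusted p = 0.255 with an estimated correlation). Of 12 marginal zone genes 9 fell, with Cd36 also Cd9 (-2.36), S1pr3 (-1.02) and the complement receptor Cr2 (-0.54), 10 when adjusted over the list alone. By camera the marginal zone list ranked lower (adjusted p = 1.98e-05; adjusted p = 0.291 with an estimated correlation). Of 5 B-1 cell genes 3 rose, Zbtb32 (3.53), Bhlhe41 (2.10) and Plscr1 (1.99), and Cd5 fell by 1.49 (3 and 1 when adjusted over the list alone). By camera the B-1 cell list ranked higher (adjusted p = 0.0286; adjusted p = 0.255 with an estimated correlation).

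Cell cycle genes fell in 22 of 31 cases in the second screen and 1 rose. Bub1 stood at 4.73 ± 0.61 in memory against 7.43 ± 0.74 in naive cells, Ccnb2 at 5.19 ± 0.32 in memory against 7.63 ± 0.84 in naive cells, Rrm2 at a change of -2.27 and Birc5 at -2.12 (26 down and 1 up when adjusted over the list alone). By camera the cell cycle list ranked lower (adjusted p = 2.14e-06; adjusted p = 0.528 with an estimated correlation). Of 10 germinal center genes 4 fell, among them the repressor Bcl6 (-1.73), the chemokine receptor Cxcr4 (-2.28) and Rgs13 (-1.21). Lmo2 rose by 0.32 (4 and 1 when adjusted over the list alone). By camera the germinal center list ranked lower (adjusted p = 0.0401; adjusted p = 0.482 with an estimated correlation). The germinal center call ended under 3 of 11 settings other than leaving out 1 array, the estimated correlation included. Naive array B stood apart in genes of the cell cycle and germinal center lists, chosen after their values were seen. S1pr2 read 9.49 on it against 6.01 to 6.93 on the other naive arrays, and Mki67 11.63 against 9.58 to 10.43. Without naive B, 22 called falls among cell cycle genes became 21 and the median of the cell cycle list moved from -0.77 to -0.60. The median of the germinal center list moved from -0.82 to -0.22 with 4 falls called.

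Interferon-stimulated genes fell in 15 of 22 cases and rose in 2 in the second screen. Ifi44 stood at 6.91 ± 0.29 in memory against 9.94 ± 0.21 in naive cells, Usp18 at 6.73 ± 0.16 in memory against 9.14 ± 0.25 in naive cells, Ifit3 at a change of -1.88 and Irf9 at -0.72 (15 and 2 when adjusted over the list alone). By camera the interferon list ranked lower (adjusted p = 1.47e-05; adjusted p = 0.255 with an estimated correlation). Extracellular purine genes rose in 7 of 11 cases and none fell. Adora2a stood at 8.14 ± 0.02 in memory against 5.65 ± 0.15 in naive cells, P2rx4 at a rise of 0.51, the ectoenzyme Enpp1 at 0.69 and Entpd1 (CD39) at 0.65 (8 when adjusted over the list alone). By camera the purine list ranked higher (adjusted p = 0.00184; adjusted p = 0.255 with an estimated correlation). Respiratory chain subunits fell in 6 of 44 cases and 1 rose (5 and 1 when adjusted over the list alone). The changes were small, at -0.40 for Uqcrh, -0.33 for Ndufa6 and -0.22 for Ndufs4. By camera the respiratory chain list ranked lower (adjusted p = 0.0401; adjusted p = 0.532 with an estimated correlation; the list not called under 5 of 11 settings other than leaving out 1 array, nor without naive B (adjusted p = 0.126), memory HJ (adjusted p = 0.0613) or I (adjusted p = 0.0805)). Immediate early genes were called in both directions, 4 up and 7 down of 19. Nr4a1 stood at a change of -2.88, Egr3 at -2.86, Dusp1 at -2.15 and Dusp2 at -1.15 (4 and 7 when adjusted over the list alone; camera adjusted p = 0.0946). Single arrays ended the calls of Enpp1 (adjusted p without naive A 0.0517), Entpd1 (adjusted p without naive C 0.0566 or memory EK 0.0644) and Ndufs4 (adjusted p without naive A 0.0505, B 0.0568, C 0.0663 or memory EK 0.0574).

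Several lists of the second screen changed in single genes without a call of the whole list. Of 26 B lineage transcription factors 3 rose and 12 fell, Bach2, Bcl6, Rel (-1.16) and Irf8 (-0.99) among the falls (4 and 13 when adjusted over the list alone). Of 27 cytokine receptors 5 rose and 9 fell. The LIF receptor Lifr stood at 8.46 ± 0.51 in memory against 3.95 ± 0.18 in naive cells, Csf2rb up by 1.43, Il21r at -1.92 and Ifnar1 at -0.56 (6 and 10 when adjusted over the list alone). Of 25 chemokine receptors and adhesion molecules 6 rose and 7 fell. Among them were the integrins Itgb1 (1.45) and Itgb7 (1.14) and the oxysterol receptor Gpr183 (1.39), all higher (7 and 8). Of 16 inhibitory receptors and phosphatases 2 rose and 4 fell, with Cd72 at 10.66 ± 0.16 in memory against 12.73 ± 0.08 in naive cells and Fcrl1 at -0.98 (2 and 5). Of 18 antigen presentation genes 4 rose and 5 fell, with the inhibitory ligand Cd274 (PD-L1) at 1.15 and Lgmn at -1.72 (4 and 5). Of 12 TNF receptors and ligands 2 rose and 4 fell, with Tnfrsf13c (the BAFF receptor) at -0.90, Lta at -0.86, Tnfrsf1b at 0.66 and Tnfrsf13b (TACI) at 0.39 (2 and 4).

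Survival and signaling genes of the second screen were also split. Anti-apoptotic factors fell in 6 of 12 cases, with Bcl2 at -0.87, Pim2 at -0.73 and Cflar at -0.70, while the kinase Pim1 rose by 1.54 (6 and 1 when adjusted over the list alone). Pro-apoptotic factors fell in 3 of 12 cases, among them Bcl2l11 and Bid (-0.78), and rose in 2, among them Pmaip1 (0.79; 3 and 2 when adjusted over the list alone). B cell receptor signaling genes rose in 2 of 25 cases and fell in 7, with Malt1 at 0.54, Pik3ap1 at -0.98 and Vav3 at -1.86 (3 and 7). Toll-like receptors and adaptors rose in 2 of 17 cases and fell in 6, with Irak3 at 1.20, Tlr1 at -0.96, Irak2 at -1.01 and Tlr6 at -0.39 (2 and 6). Quiescence genes rose in 4 of 19 cases and fell in 5, with Foxo1 at -1.26, Klf3 at 0.75 and Klf6 at 0.62 (5 and 6). Genes of antibody-secreting cells rose in 2 of 13 cases, Jchain (3.36) and Txndc5 (1.31), and fell in 3, among them Derl3 (-2.02) and Ell2 (-0.36), with 2 and 4 when adjusted over the list alone. Camera gave no call to any of these 6 lists. Genes of antibody-secreting cells had a median of -0.01 and a mean of 0.15 (camera up). Pro-apoptotic factors had a median of 0.00 and a mean of -0.20 (camera down), and cytokine receptors a median of -0.13 and a mean of 0.04 (camera down). Chemokine receptors and adhesion molecules had a median and a mean of -0.07 (camera up), and antigen presentation genes a median of -0.08 and a mean of 0.17 (camera up). Quantile normalization turned the camera direction of antibody-secreting cell and antigen presentation genes downward (adjusted p = 0.949 and 0.893), and brought the median of the former to 0.03.

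Genes listed as markers of other cells moved with the groups of the second screen, and which cells carried their transcripts was not tested. Of 13 T cell genes 7 fell and Cd2 rose by 1.25, to a high level of 12.36 to 12.54 on the memory arrays. Lck stood at 6.89 ± 0.32 in memory against 8.90 ± 0.27 in naive cells and Cd3g at a change of -1.77 (9 down and 1 up when adjusted over the list alone). By camera the T cell list ranked lower (adjusted p = 0.0438; adjusted p = 0.607 with an estimated correlation; the list not called under 5 of 11 settings other than leaving out 1 array, nor without naive B (adjusted p = 0.0728), D (adjusted p = 0.104), memory EK (adjusted p = 0.0545), FG (adjusted p = 0.0574) or I (adjusted p = 0.0592)). All 5 measured NK cell genes fell. Gzma stood at 6.34 ± 0.83 in memory against 8.83 ± 0.34 in naive cells, Ccl5 at 7.26 ± 0.22 in memory against 8.99 ± 0.30 in naive cells, Nkg7 at a change of -1.33 and Il2rb at -1.30 (5 when adjusted over the list alone). By camera the NK cell list ranked lower (adjusted p = 0.000811; adjusted p = 0.321 with an estimated correlation). In the dendritic cell list 3 of 6 genes fell, Cd83 (-1.27), Flt3 (-0.56) and Klrd1 (-1.52), a receptor gene of NK cells (3 when adjusted over the list alone). By camera the dendritic cell list ranked lower (adjusted p = 0.0438; adjusted p = 0.291 with an estimated correlation; the list not called without naive A (adjusted p = 0.0647), B (adjusted p = 0.0707), D (adjusted p = 0.0635) or memory FG (adjusted p = 0.0574)). Without Klrd1, a setting chosen after seeing the data, the dendritic cell list was not called (adjusted p = 0.143; adjusted p = 0.446 with an estimated correlation). Of 17 myeloid genes Cd68 rose by 0.89 and Spic fell by 0.97 (1 and 1 when adjusted over the list alone). Car2 fell by 2.24 among 6 erythroid genes (1 when adjusted over the list alone), and none of 3 platelet genes was called (Gp1bb (0.16), Pf4 (-0.06); 0 when adjusted over the list alone). No Y-linked gene passed the filter on dim probe sets. Cd79a (-0.02, adjusted p = 0.93) and Ighm (-0.05, adjusted p = 0.695) were not called. Of 2 immunoglobulin constant regions Ighg1 was the 1 called (1 when adjusted over the list alone).

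**Figure D3:**
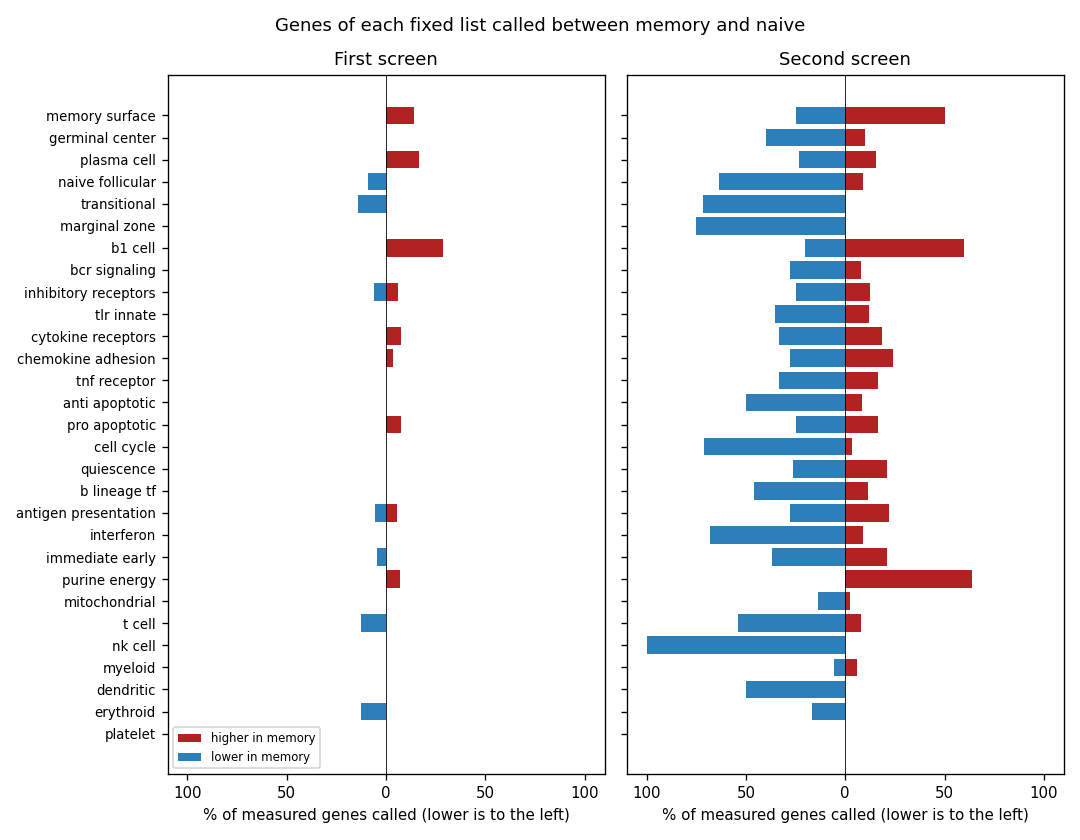
Share of the measured genes of each fixed list that were called higher (red, right) or lower (blue, left) in memory cells, in percent, per screen, for lists with at least 3 measured genes in both screens. Among cell cycle genes 0 of 32 were called in the first screen and 22 of 31 were called lower in the second.

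By limma with Benjamini-Hochberg adjustment, 3906 of 14706 genes and unassigned probe sets were called in the second screen, 1543 higher and 2363 lower in memory cells, with 354 and 458 changed at least 2-fold. After quantile normalization 1806 were higher and 1982 lower. Unadjusted, 5602 had a p under 0.05. Memory and naive arrays did not overlap for 29.4% of all tested, where chance gives 2.86%. The naive and memory cells of this screen also differ in the mice they came from, so the transfer, the Jk deletion and the memory state cannot be separated by this comparison. The count fell to 1817 when the spread was shared with the first screen, and camera called 12 lists, 11 without Klrd1 in the dendritic cell list and 0 with an estimated correlation.

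The screens share no arrays, and their overlap asked which changes were found in both. For the overlap each screen used its own brightest probe set of a gene, so a gene could be read on different probe sets. Plscr1 thus rose by 1.62 in the first and 1.99 in the second screen. Its change differed by 0.86 in the test of the difference, which used the same probe set in both screens. Of 13055 genes and probe sets measured in both, 95 were higher in memory cells of both screens where 10.8 would be expected (Fisher's exact test, two-sided p = 4.08e-87) and 27 lower in both where 4.95 would be expected (p = 4.62e-19, exact). None was called in opposite directions, against 16.9 expected up in the first and down in the second (p = 1.73e-08, exact) and 3.15 the other way (p = 0.0678, exact). Immunoglobulin genes and Jchain aside, the named genes with the largest shared rises were S100a4, Tppp, Hepacam2, S100a6, Pdlim1, Tubb6, Emp1, Prkar2b, Ass1 (2.63 and 3.72) and Zbtb32 (2.65 and 3.53). The largest shared falls were in Tifa, Vpreb3, Csrp2, Cpm (-1.63 and -2.60), Ifi44l (-1.37 and -2.82), Selenop (-1.51 and -2.65), Egr3, Ly6a, Rgs10 and Sapcd1 (-1.46 and -2.11). In the first screen leaving out 1 array ended the calls of Ifi44l (adjusted p without naive A 0.11, B 0.114, memory E 0.0633 or F 0.0563) and Rgs10 (adjusted p without naive A 0.147, B 0.186, memory E 0.101 or F 0.123). Across genes, which are not independent replicates, the changes of both screens correlated with a Pearson r of 0.56 and a Spearman rho of 0.44. Of 128 genes called in the first screen and measured in both, 127 had the same sign in the second. The shared count of 122 was 65 without naive A, 54 without naive B, 68 without memory D, 75 without memory E and 59 without memory F of the first screen. It was 526 with naive C and memory G as a block, and 550 without both. Opposite calls numbered 3 and 8 in these 2 settings, 13 with array weights, 2 with all 15 arrays in 1 fit, and 1 each without the trend, without naive C and without memory G of the first screen.

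**Figure D4:**
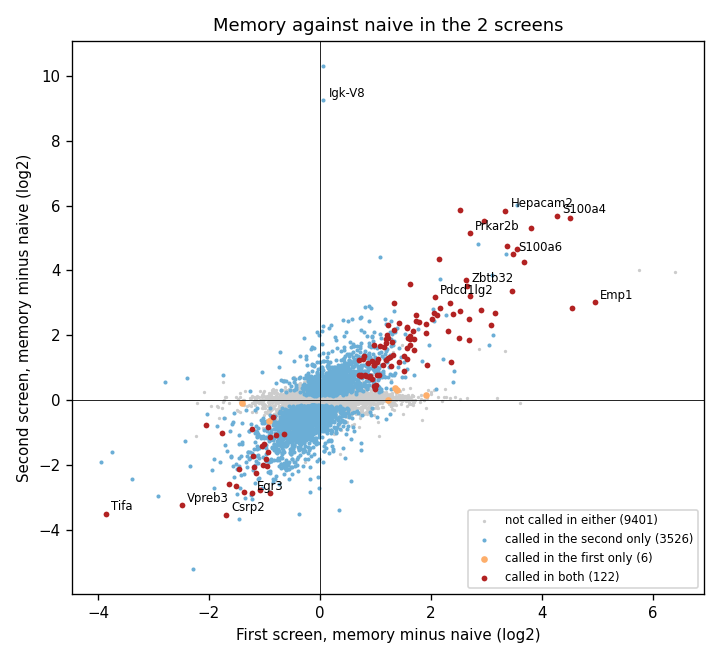
Change of each gene or unassigned probe set measured in both screens, memory minus naive on the log2 scale, the first screen on the x axis and the second on the y axis; colors give the screen in which it was called. The 122 called in both lie in the quadrants of equal sign, and Igk-V8 stands near 0 in the first screen and at 9.25 in the second. A gene is read on the brightest probe set of each screen, which can differ between the screens.

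The test of the difference between the screens asked where the measured memory change differed. The brightest probe set named Igk-V8, a kappa light chain variable region, changed by 0.06 in the first screen and by 9.25 in the second, where naive cells stood at 3.07 ± 0.37 (difference 9.18 ± 0.26, adjusted p = 1.13e-11). Whether that probe set also takes up signal of other kappa chains was not tested. Ly6a (Sca-1) fell by 1.07 in the first and 2.77 in the second screen (adjusted p = 4.84e-05) and Rgs10, a regulator of G protein signaling, by 0.90 and 2.85 (adjusted p = 6e-05). Prkar2b rose by 2.70 and 5.15 (adjusted p = 0.000121). The cyclin Ccnd2 changed by -0.11 in the first and rose by 1.60 in the second screen (adjusted p = 0.000732), and Cd2 by 0.39 and 1.25 (adjusted p = 0.00247). The other named genes with the smallest adjusted p were Igsf9 (difference 2.04, adjusted p = 6.62e-05), Cyp4f18 (1.32, 8.82e-05), Anp32a (1.90, 0.000131) and Relt (1.54, 0.000261), all higher in the second screen.

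In all, 168 of 12974 genes and probe sets were called for this difference by limma, 71 with a higher and 97 with a lower change in the second screen, and 1628 had an unadjusted p under 0.05. On simulated data 21.0% of the calls of this test were false, above the 5% aimed at, against 9.34% for a test with the degrees of freedom of each separate fit, chosen after seeing the data. That test called 133, 121 of them among the 168 and all 10 genes named above. The count was 101 without naive B, 528 without naive C and 392 without memory G of the first screen. For the second it was 107, 105 and 88 without naive A, B and C and 76, 109 and 104 without memory EK, FG and I. With naive C and memory G of the first screen as a block, chosen after seeing the data, the count was 634 (263 higher and 371 lower). Without both arrays it was 1224. Median centring gave 57, of which 43 were higher and 14 lower in the second screen.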

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

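The tests of the control probe sets and of the kappa light chain probe sets, the block of naive C with memory G, and the difference test with its own degrees of freedom were chosen only after the results were seen. Of the 35 splits of the 7 arrays of the first screen, 1, the real one, gave as many called genes (131, highest other 2). Of the 35 splits of the second screen it was also 1 (3906, highest other 0). Every other split put memory and naive arrays together on at least 1 side, which adds the group difference to the spread. The smallest share possible is 1 of 35, so the splits do not exclude chance for either count. Those of the first screen also took no account of how naive C and memory G stood apart. For the difference between the screens, 6 of 100 drawn splits, the real one included, gave as many as the real 168. All 5 others left the groups of the second screen intact and so still held its memory effect, and the highest with mixed groups in the second screen gave 123, so the splits leave open whether chance can be excluded for that count. The highest other split gave 1935, several times the real count. It kept the parting of naive and memory cells in the second screen. The real split kept it too, so that parting alone does not account for 1935. How the arrays of the first screen fell in that split was not examined.

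Naive C and memory G of the first screen stood apart from the other arrays of that screen. Their actin 3′/5′ ratios were 1.15 and 1.12 and their Gapdh ratios 0.865 and 0.799, and the lowest actin ratio of the other 5 arrays was 2.42 times the higher of theirs. Labeled fragments that reach further from the 3′ end are a candidate explanation. An exchange of their labels is argued against: over 160 genes changed at least 4-fold in the second screen, memory G minus naive C had a median of 1.54 in the second screen's direction and was above 0 for 95.6% of them. No biological explanation was tested, as the labels give no difference between these and the other arrays. With both arrays as a block 707 genes were called and without both 879, against 131, each including all 131. On the other 5 arrays both ratios were higher on every naive than on every memory array. The counts of 707 and 879 may therefore hold that difference too, which was not tested.

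Of 7 kappa light chain probe sets above the threshold on all arrays of the first screen, 5 were higher by more than 1 in memory cells of the second screen, and the 7 differed by at most 0.37 in the first. In the second screen 3 Igk-V8 probe sets reached 12.32, 12.38 and 11.12 in memory cells against 3.07, 2.22 and 2.79 in naive cells, and another rose by 1.34. These 3 read 15.15, 14.35 and 14.35 in naive cells of the first screen, where that other one read 8.81. Whether the 3 also take up signal of other kappa chains was not tested, so their rise need not be that of Igk-V8 alone. Igk-V1 rose by 2.22, from 2.89 to 5.11, and Igk-V38 by 0.15, from 3.40 to 3.55. Of the 7, 6 lay below the threshold (4.73) on all second-screen naive arrays. The remaining Igk-V8 probe set stood at 5.67 in naive and 6.22 in memory cells of the second screen, against 10.37 in naive cells of the first, and lies too near the threshold to decide. The Jk deletion of the naive mice may explain the low naive signal, and stays open. Cells of the Vk8R recipients in the memory sort would raise Igk-V8 and leave Igk-V1 at its naive level. Igk-V1 rose, but on 1 probe set that may share signal with Igk-V8, which was not tested, and Igk-V38 stayed near its naive level. The values therefore cannot decide on such cells. For the Igk-V8 rise, recipient cells and the kappa chains of the memory cells themselves cannot be told apart, as the recipients and the memory state coincide in the design. The difference in mice between naive and memory cells stays open as a biological explanation.

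Of 31 cell cycle genes 22 were lower and 1 higher in memory cells of the second screen, and of 10 germinal center genes 4 were lower and 1 higher. Neither list was called with an estimated correlation (camera adjusted p = 0.528 and 0.482). Naive B held the highest naive values of S1pr2 (9.49), Efnb1 (9.27) and Mki67 (11.63). Germinal center-like cells in naive B alone are argued against for the cell cycle list, of which 21 genes were called lower without naive B and 22 with it. The median of that list moved from -0.77 to -0.60 without naive B, so how much of the fall naive B adds stays open. For the germinal center list such cells stay open, as its median moved from -0.82 to -0.22 without naive B while 4 of its genes were called lower. The median of the cell cycle list was -0.76 after quantile normalization. The arrays of the second screen already had near equal median intensities before that step (24.99 to 26.02). It could therefore change little, and cannot decide whether earlier scaling between arrays played a part. A difference in division between naive and memory cells, or between the mice, stays open and was not tested.

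Arrays far from the other 3 of their group were found for 28 of 355 groups of values, where chance alone gives about 1 in 20, or 17.8; all but 1 are given, each with its gap over the range of the group (Dixon's ratio), its log2 intensity and the range of the others. In memory cells of the first screen array G held Emp1 (0.955; 7.51 against 8.27 to 8.31), Tnfrsf1b (0.836; 9.75 against 8.97 to 9.10), Cd79a (0.861; 15.01 against 13.78 to 13.95), Tlr1 (0.831; 11.70 against 12.20 to 12.30), Top2a (0.854; 9.34 against 9.83 to 9.92), Ifi44 (0.848; 10.31 against 9.37 to 9.52) and Vpreb3 (0.883; 8.96 against 9.61 to 9.70). Array D held Kdm5d (0.852; 9.55 against 7.51 to 7.81) and Ifi44l (0.847; 8.81 against 9.40 to 9.50). Array E held Tifa (0.887; 5.23 against 4.41 to 4.50). In memory cells of the second screen array EK held S100a4 (0.85; 13.09 against 12.89 to 12.92), Osbpl3 (0.836; 9.30 against 8.73 to 8.82), Cd2 (0.832; 12.36 against 12.51 to 12.54) and Cd27 (0.919; 3.83 against 4.42 to 4.47). Array FG held Gzma (0.849; 5.11 against 6.61 to 6.88). Array HJ held Tppp3 (0.945; 8.86 against 10.05 to 10.12), Pmaip1 (0.83; 10.64 against 10.36 to 10.41), Foxo1 (0.861; 10.02 against 9.79 to 9.82) and Il7r (0.845; 5.64 against 5.14 to 5.22), and array I held Ndufs4 (0.834; 9.76 against 9.68 to 9.69) and Ly6a (0.869; 9.83 against 10.12 to 10.16). In naive cells of the second screen array B held D430019H16Rik (0.945; 4.03 against 3.07 to 3.13), array C held Cd80 (0.879; 3.90 against 4.72 to 4.83) and Lgmn (0.853; 10.50 against 10.67 to 10.70), and array D held Igsf9 (0.93; 5.31 against 5.04 to 5.06), Irak2 (0.889; 8.75 against 9.33 to 9.40) and Cxcr4 (0.844; 9.97 against 11.45 to 11.72).

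The change between memory and naive cells differed between the screens, by the limma contrast of both changes, for 34 named genes; values are the change in the second minus that in the first screen on the log2 scale. Higher in the second screen were Anp32a (1.90), Ass1 (1.09), Ccnd2 (1.71), Cd2 (0.87), Cyp4f18 (1.32), Hepacam2 (2.50), Igk-V8 (9.18), Igsf9 (2.04), Pdcd1lg2 (1.10), Pde2a (1.30), Pim1 (1.10), Prkar2b (2.44), Relt (1.54) and S100a6 (1.02). Lower were BC030863 (-3.13), Bcl2 (-0.83), Bcl2l11 (-1.60), Btla (-0.63), Cd36 (-2.92), Cd5 (-1.72), Cpm (-0.96), Csrp2 (-1.85), Derl3 (-1.72), Egr3 (-1.63), Fcrl1 (-0.71), Gzma (-3.04), Ifi44 (-1.81), Ifi44l (-1.45), Il12a (-1.67), Lck (-1.06), Ly6a (-1.70), Rgs10 (-1.95), Selenop (-1.15) and Usp18 (-1.31). With the degrees of freedom of each separate fit Bcl2 (adjusted p = 0.0767) and Fcrl1 (adjusted p = 0.0661) were not called and the other 32 were. With naive C and memory G as a block, chosen after seeing the data, all 34 stayed called and further named genes were called. Among those were H1f2 (adjusted p = 0.000266), Cd72 (adjusted p = 0.00146), Pdlim1 (adjusted p = 0.0069) and S100a4 (adjusted p = 0.015). The screens also differ in mice, sorter, labeling and intensity scale, and the naive cells are labeled AA4.1-negative in the second screen only. None of these can be separated for these genes. GCRMA is given for the second screen only, so the treatment of low signals may also differ and alter the size of a change.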

How the results depend on the processing

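The block of naive C with memory G, the fit without both, the dendritic cell list without Klrd1, and the difference test with its own degrees of freedom were chosen only after the results were seen. No paired analysis was possible because replicate letters do not repeat between naive and memory of a screen. The use of another table was not run, since the deposited tables hold pooled columns, a ratio and a p-value but no value per array.

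The first screen's 131 called genes became 65 with median centring, 909 with array weights, 1034 with all 15 arrays in 1 fit, 54 with a t-test, 707 with the block and 879 without naive C and memory G. Leaving out 1 array gave 58 (without naive B) to 150 (without memory G). Its 11 called lists became 0 with an estimated correlation and 6 with fry. The second screen's 3906 genes became 1817 with all 15 arrays in 1 fit, 812 with a fold change of at least 2 as well. Leaving out 1 array gave 2995 (without memory EK) to 4210 (without naive D). Its 12 lists became 6 with the stricter filter, 0 with an estimated correlation and 20 with fry. The 122 shared genes became 60 with median centring, 73 without the trend, 580 with array weights, 489 with all 15 arrays in 1 fit, 47 with a t-test, 526 with the block and 550 without naive C and memory G. Leaving out 1 array gave 54 (without naive B of the first screen) to 136 (without memory G). The 168 differences became 269 without a filter, 57 with median centring, 466 as the difference of the 2 separate fits, 634 with the block and 1224 without naive C and memory G. Leaving out 1 array gave 76 (without memory EK) to 528 (without naive C of the first screen), and the test with its own degrees of freedom gave 133. The cause was not tested, except that leaving out arrays lowers the number of samples and a filter changes the number of genes tested.

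The other planned counts stayed within 1.5 times: 90 to 142 in the first screen, 2869 to 5444 in the second. Cd93 in the first screen turned from 0.34 to -3.21 with the stricter filter, -2.92 with a pseudocount of 16 and -2.05 as the mean of its probe sets, since another of its probe sets then stood for it or shared in it. Of 43 called named genes of the first screen 13 stayed called under every setting fixed beforehand other than leaving out an array, among them S100a6, S100a4, Ighg1, Zbtb32, Pdcd1lg2 and Vpreb3, and of 130 in the second 91. Of the 11 and 12 called lists none did, as all lost the call with the estimated correlation. Counting that setting, first-screen calls ended under 7 (transitional), 5 (receptor signaling), 3 (immediate early and purine) and 2 settings (cell cycle). Those of the second screen ended under 5 (respiratory chain and T cell), 3 (germinal center) and 2 settings (B-1 and dendritic cell). The other called lists lost the call under 1 setting. On simulated data the first screen recovered 24.6% of genes changed 2-fold and 61.3% of those changed 4-fold, with 4.06% of calls false; the second recovered 90.5% and 99.2%, with 5.37% false. The difference test recovered 46.3% and 84.5% with 21.0% of calls false, and 37.1% and 76.5% with 9.34% false with its own degrees of freedom. These shares hold for independently drawn genes and need not hold for the real arrays, where naive C and memory G of the first screen stood apart. Signal over background limits changes of dim probe sets, for which naive or memory values lie below the median.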

Other observations

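The values below were chosen only after they were seen, and no explanation was tested. In the first screen's deposited table the ratio was at least 2 for 9098 probe sets, against 4469 by the ratio of means, and at most 0.5 for 762 against 1843; its median was 1.41 against 1.06. With a deposited p under 0.05 as well, 1456 against 907 had a ratio of at least 2 and 260 against 475 a ratio of at most 0.5. The deposited p was under 0.05 for 3299 probe sets in the first and 9571 in the second screen, of which 7 and 2611 stayed under it after Benjamini-Hochberg adjustment.

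Crisp1 stood at 6.76 in memory and 5.35 in naive cells of the first screen and at 11.35 and 3.91 in the second. Iglv1, a lambda light chain variable region, stood on its brightest probe set at 15.43 and 15.41 in naive and memory cells of the first and at 15.41 and 15.44 of the second screen. Of Y-linked genes in the first screen, Ddx3y read 11.73 on memory D, 8.85 to 9.83 on the other memory arrays and 10.39 to 10.63 on the naive arrays. Eif2s3y read 11.51 on memory D, 8.51 to 9.70 on the other memory arrays and 9.96 to 10.13 on the naive arrays. The same Ddx3y probe set averaged 3.36 and 3.41 in the second screen's groups. Hba-a1 read 14.79 on memory D of the first screen, 12.65 to 13.37 on its other memory arrays and 10.79 to 12.29 on its naive arrays. S100a8 averaged 9.75 in memory and 6.41 in naive cells of the first and 11.38 and 9.85 of the second screen.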
